A study of Mus musculus with 30 samples.

How the data were processed

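The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, in 5 mouse embryonic stem cell lines of the C57BL/6 strain. The lines were wild type (WT), a knockout of Mettl14 (KO), and the knockout with METTL14 put back as the wild-type protein (KO+WT) or as either of 2 arginine mutants (KO+5RK and KO+13RK). METTL14 is the RNA-binding partner of METTL3 in the complex that deposits m6A. The names 5RK and 13RK are those of the labels, and the series title places arginine methylation in the disordered C-terminus of METTL14. Each line has 3 libraries from immunoprecipitation with an m6A antibody and 3 input RNA libraries, 30 libraries in all. The values analysed were the 15 peak lists, one for each immunoprecipitated library. Expression in the input libraries was not analysed here.

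Per the labels' protocols, messenger RNA was purified, fragmented chemically, immunoprecipitated with a polyclonal m6A antibody, and made into stranded libraries. The submitters' processing notes name STAR 2.5.3a, kallisto 0.43.0 and the mouse build GRCm38, without giving their roles. How the peaks were called beyond that is not given in the sources used here. The names of the deposited lists contain the word clam, and no label or header says whether this names the peak caller. The deposited lists have no header. Each row is a bin of 100 nt within an Ensembl gene, with an enrichment value, a p and a q. The enrichment value is a score of the authors' own, from 0.31 to 5.82 over all lists, and 17.4% of the values lay below 1. Its scale, linear or logarithmic, is not given, so it was used only to rank or filter peaks within a list. The deposited p-value and q-value of each bin were used in the same way, and every deposited q was under 0.05. Each of the authors' lists carries the name of one replicate, so peaks were compared replicate by replicate. Read depth and coverage per peak are unknown, so no counting interval is given and the absence of a call is not the absence of m6A.

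Only the presence or absence of a called bin was compared between lists. A gene was counted once per list however many bins it had. Regions were made by merging bins that overlapped by 1 nt or more on the same strand over the 15 lists, which turned 62091 distinct bins into 60022 regions. Gene symbols came from a name table that matched 99.7% of the 13765 genes with a bin in any list, leaving 35 without a symbol. Distances to the start and end of a gene used RefSeq gene spans of the same build, matched by symbol, with the strand of the bin. A bin was called near the gene start within 500 nt of it and near the gene end within 2000 nt. No genome sequence or transcript annotation was used here, so transcript parts and sequence motifs were not analysed here. The distance measure was chosen in their place after the files had been seen.

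A gene or region was counted as lost between lines when it was called in all 3 lists of the first line and in none of the 3 lists of the second, and as gained in the reverse case. Means of 3 lists were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1, so that no such comparison could pass 0.05. Differences over the 5 lines were tested by permuting the lists 100000 times against an F statistic. The 6 lists with wild-type METTL14 (WT and KO+WT) were compared with the 6 arginine mutant lists by a two-sided exact permutation test, with a smallest p of 0.0021645. Per gene, the same 6 and 6 lists were compared by Fisher's exact test over genes called in at least 3 of them. A Fisher's exact test of the 3 KO lists against the 12 others, per gene and per region, was added after the files had been seen. So were the tests of the regions called in the rescue lines and of the share of peaks within gene lists. The p-values of each family were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

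The 14 gene lists and the rule for named genes were fixed before the data were examined. The rule took 11 genes of the m6A and pluripotency fields always, up to 4 lost or gained members of each gene list, and the 5 lost and 5 gained genes with the highest within-list percentile of the enrichment value. Other genes are named as chosen after their values were seen. The alternatives tried were a stricter q of 0.005, an enrichment value at or above the median of all peaks (1.36), leaving out each replicate, the replicate number as a block, lists of equal length (the 6328 peaks with the smallest p), calls in 2 or more lists, protein-coding genes only, and unmerged bins.

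The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries. On simulated calls, 200 genes were set as called in every list of one side of a comparison and in none of the other. They meet the rule of 3 lists against 0 by construction. Its recovery of 200 of the 200 from WT to KO, over 13765 genes, was therefore fixed in advance. The rule also counted 88 unchanged genes there, 68 from KO+WT to KO+5RK and 70 from KO+WT to KO+13RK. The pooled Fisher's exact test of 6 against 6 lists recovered 0 of the 200 over 9222 simulated genes that passed the filter. The test of 12 lists against KO recovered 0 of the 200 over 9834 genes and 0 of the 200 over 25698 regions. At the smallest p that these tests can give, 200 genes or regions are too few to pass the adjustment. These counts of 0 were therefore also fixed by the number chosen, and larger numbers can pass. A count of 0 from these tests carries little information. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.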

Results

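The 15 lists held 204208 called m6A peaks in all. WT cells had the most, with 22683 ± 474 peaks per list (mean ± SD, n = 3), and the Mettl14 knockout the fewest, with 7777 ± 1258. The knockout with wild-type METTL14 put back had 15206 ± 1714 peaks. The arginine mutants lay between it and the knockout, with 12298 ± 985 in KO+5RK and 10105 ± 762 in KO+13RK. Genes with a peak followed the same order, from 7846 ± 54.4 in WT through 6540 ± 474 in KO+WT, 5893 ± 235 in KO+5RK and 5274 ± 273 in KO+13RK to 4373 ± 586 in KO. The lines differed in both measures (permutation test over the 15 lists, p = 1e-05, the smallest that the resamples can give). No 2 lines had overlapping peak numbers in the 8 comparisons made. Similarity was measured as the Jaccard index, the genes with a peak in both lists over those in either. Its median within a line was 0.670 in WT, 0.392 in KO, 0.564 in KO+WT, 0.501 in KO+5RK and 0.466 in KO+13RK. Between lines it was 0.376 for WT with KO, 0.541 for KO+WT with KO+5RK and 0.484 for KO+WT with KO+13RK. Lists of each mutant were thus no more like each other than like KO+WT lists.

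**Figure D1:**
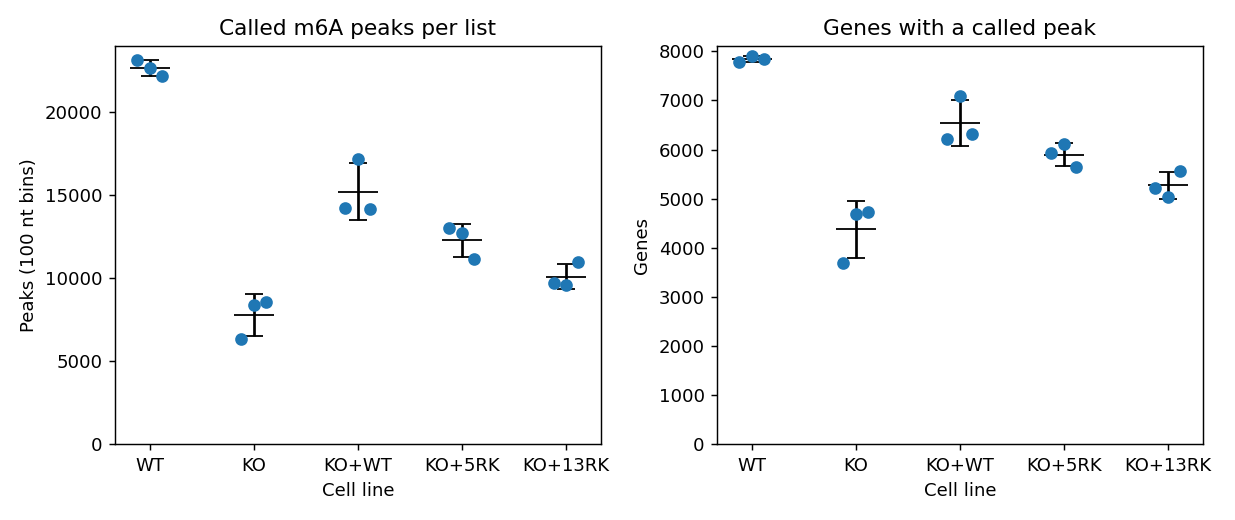
Called peaks (left panel, number of 100 nt bins) and genes with a called peak (right panel, number of genes) in each of the 3 lists of a cell line. Points are lists and bars are the mean and SD; the WT lists hold 22217 to 23164 peaks and the KO lists 6328 to 8593.

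The knocked-out gene could not be checked from these lists. Mettl14 had a peak in 2 KO+5RK lists and in no other list, and a peak call does not report expression. Of the other genes followed in every line, Nanog was called in 3 lists of each line except KO+13RK, where it was called in 2. Esrrb was called in every list, with 8.67 ± 0.577 bins per list in WT, 9.33 ± 1.53 in KO, 11 ± 2.65 in KO+WT, 5.33 ± 2.08 in KO+5RK and 2.67 ± 1.15 in KO+13RK (n = 3). Sox2, Klf4 and Klf2 were called in 3 lists of every line but KO, where each was called in 2. Mettl3 and Pou5f1 had no peak in any WT list, and Myc was called in 1 WT list and in all 3 KO+WT lists.

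Removing METTL14 asked which peaks depend on it. The KO lists held 65.7% fewer peaks than the WT lists, and 1775 genes with a peak in all 3 WT lists had none in any KO list, against 94 in the reverse direction. With every list reduced to its 6328 peaks of smallest p, which removes any general difference in peak number, these counts were 584 and 504. Among the lost genes were Fancm, Brip1, Rev3l and Atrip of the crosslink repair list, the exonuclease Exo1, the mismatch repair gene Mlh3, and the long noncoding RNAs Tug1 and Meg3. Of members called in all WT lists, 25% were lost in crosslink repair and 12.9% in homologous recombination. The share was 15.6% in excision and mismatch repair and 42.9% in end joining (3 of 7 members). Among other genes it was 31.5% to 31.6%. Fancm had 5.67 ± 2.08 bins per list in WT and Rev3l 6.33 ± 2.89 (n = 3), with no bin in the KO lists. The pluripotency factor Tbx3 had 4.00 ± 0 bins in WT and the growth factor gene Fgf4 had 3.33 ± 1.15, again with none in KO. The lost genes with the highest enrichment percentile included Atp2c1, Rngtt, Rasa1 and Ptpn4, and the bin of Atp2c1 lay on chromosome 9 at 105412740 to 105412839 (GRCm38), 1427 nt from the end of the gene. The gained genes with the highest percentile were Gm6542, Sema6a, Gm44492, Lpcat4 and Slc17a5, and the germ cell and naive pluripotency gene Dppa3 was also gained. Dppa3 was called as well in 2 KO+WT, 3 KO+5RK and 2 KO+13RK lists, and Lpcat4 in 2, 2 and 1. The other gained genes named here were called in at most 1 list of each of these lines. The exact permutation p of the peak numbers was 0.1, the smallest that 3 lists against 3 allow.

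At the level of regions, 8744 of the 10946 regions called in all WT lists (79.9%) were called in no KO list. Against the 12 lists of the other lines together, 1123 regions in 822 genes were called less often in KO and 248 more often (Fisher's exact test, adjusted p = 0.0384 for each, 23941 regions tested). Each of these 1123 regions was called in all 12 lists and in no KO list. They included regions of Brca1, Fancl and Rev1 in crosslink repair and of Klf4, Esrrb, Sall4 and Nr5a2 among the pluripotency factors, genes chosen after their values were seen. Brca1 also had 1 region called more often in KO. Of the genes with any peak, 10 of 38 in the pluripotency list, 10 of 39 in homologous recombination, 8 of 46 in crosslink repair, 11 of 62 among chromatin modifiers, 7 of 39 in the cell cycle, 6 of 45 in signalling and 4 of 45 in excision and mismatch repair had such a region. So had 3 of 10 noncoding RNAs, 2 of 15 arginine methyltransferases, 2 of 25 in the m6A machinery, 1 of 10 in end joining, and 0 of the primed state, fibroblast and ribosomal protein lists. Over all 13765 genes with a peak in any list the number was 822, and the lists were not tested against it. A region called more often in KO occurred in 4 chromatin modifiers, 3 homologous recombination genes, 2 of the m6A machinery, and 1 each in crosslink repair, arginine methyltransferases, the cell cycle and fibroblast markers. The test can pass only with all 3 KO lists, and without KO replicate 1, 2 or 3 it called 0 regions. At the stricter q it called 655 regions in place of 1371. The same test per gene called 0 of 9852 genes, with 1440 at an unadjusted p under 0.05. Among them 325 genes were called in all 12 lists and in no KO list, at the smallest adjusted p that occurred, 0.0633. In simulated calls this Fisher's exact test recovered 0 of 200 changed genes, a number too small to pass the adjustment.

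The peaks left in the knockout were placed differently along genes. Within 500 nt of the gene start lay 17.5% ± 1.03 of the placed KO peaks (n = 3), against 4.76% ± 0.556 in WT, 5.66% ± 1.60 in KO+WT, 6.14% ± 0.936 in KO+5RK and 7.07% ± 1.62 in KO+13RK (permutation test over the 15 lists, p = 0.00253, adjusted p = 0.00325 over 9 measures). In number, 1207 ± 262 peaks per list lay near the gene start in KO and 948 ± 94.6 in WT (n = 3), so the numbers differed much less than the shares. Within 2000 nt of the gene end lay 17.0% ± 1.47 of the KO peaks and 34.6% ± 0.399 of the WT peaks (permutation p = 0.00058). Of the 2300 regions called in all KO lists, 1055 (45.9%) were also called in all WT lists and 594 (25.8%) in none. WT regions that were also called in all KO lists lay near the gene start in 18.4% of 874 cases, against 1.04% of 7917 WT regions absent from KO (Fisher's exact test over regions, odds ratio 21.6, p = 3.46e-105). Regions of one gene are not independent. Mat2a, which encodes the enzyme that makes S-adenosylmethionine and carries m6A placed by METTL16, was called in every list, with 6.00 ± 1.00 bins in WT and 4.33 ± 0.577 in KO (n = 3).

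**Figure D2:**
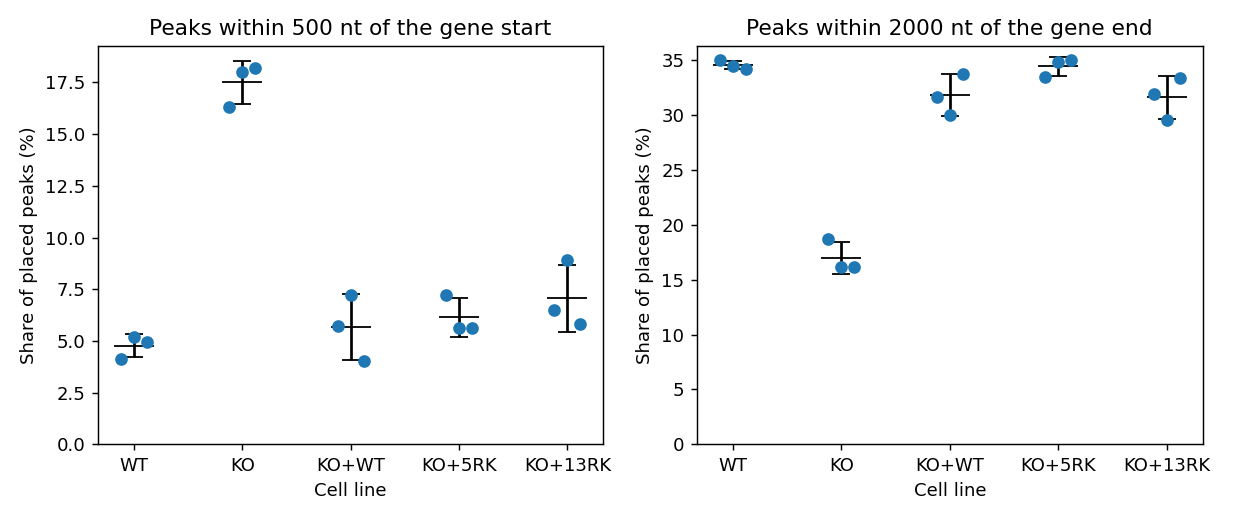
Share of placed peaks within 500 nt of the gene start (left, percent) and within 2000 nt of the gene end (right, percent) in each list. Points are lists and bars are the mean and SD of 3 lists; the KO lists have 17.5% near the start and 17.0% near the end.

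The wild-type rescue asked how much of the WT pattern returned when METTL14 was put back. The KO+WT lists held 33.0% fewer peaks than the WT lists, and the KO lists 48.9% fewer than KO+WT (exact permutation p = 0.1 for each, n = 3 per line). Between KO+WT and KO, 1030 genes were lost and 109 gained, and at equal list length 500 and 325. The lost genes with the highest enrichment percentile were the ubiquitin ligase gene Uhrf2, the calcium pump gene Atp2c1, Mtmr10, Prcp and Gm27937, an uncertain call since it overlaps the Tug1 locus, and Sema6a, Gm44492, Slc17a5, Dtx4 and Gm15122 led the gained genes. Between WT and KO+WT, 329 genes were lost and 59 gained. At equal list length these counts were 84 and 116, so that losses no longer outnumbered gains. Equal length removes a general loss of peaks whatever its cause, so this balance does not exclude one. WT also had more peaks in fibroblast markers, with 32.3 ± 4.51 per list against 7.33 ± 3.79 in KO and 5.33 ± 0.577 in KO+WT (n = 3), most of them in the fibronectin gene Fn1, with 25.3 ± 4.04 in WT.

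The arginine mutants asked whether changing these arginines of METTL14 alters the m6A pattern that the protein restores. The KO+5RK lists held 19.1% fewer peaks than KO+WT and the KO+13RK lists 33.5% fewer, and KO+13RK had 17.8% fewer than KO+5RK (exact permutation p = 0.1 for each, n = 3 per line). The 6 lists with wild-type METTL14 averaged 18945 peaks and the 6 mutant lists 11201 (exact permutation p = 0.00216, adjusted p = 0.00487 over 9 measures). WT and KO+WT are different lines, so this comparison does not separate the mutations from other differences between lines. From KO+WT to KO+5RK, 112 genes were lost and 54 gained, and other ways of parting the same 6 lists gave up to 154 genes against the 166 observed. From KO+WT to KO+13RK, 288 genes were lost and 38 gained. At equal list length 54 genes were lost and 69 gained in KO+5RK, and 97 lost and 108 gained in KO+13RK. There, losses outnumbered gains in neither mutant. Equal length takes away any general difference in peak number, whatever its cause. This balance therefore does not argue against a loss in the mutants.

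Both mutants lacked the checkpoint kinase gene Chek1 and the histone demethylase gene Kdm4c, which were called in all 3 KO+WT lists. KO+5RK also lacked the recombination genes Palb2 and Rnf168, the transcription-coupled repair gene Ercc6 and the Polycomb methyltransferase gene Ezh2. KO+13RK also lacked Gtf2h1, Cbll1, Mettl16, Prmt7, Fn1, Grb2, Rpsa, Rplp2 and Xist. Some of these were weak calls in KO+WT by mean enrichment percentile. The percentile was 20.7 for Chek1, 15.9 for Ezh2, 13.0 for Fn1, 11.7 for Mettl16, 10.6 for Rpsa and 2.57 for Rplp2. The others lay between 34.1 (Grb2) and 88.9 (Prmt7). Of the genes lost in KO+5RK 50% were called in no KO list, as were 44.8% of those lost in KO+13RK and 25.7% of all genes called in the 3 KO+WT lists. These shares are not matched for peak strength. Regions absent from KO were also lost more often from a single replicate of a line, with odds ratios of 1.27 to 3.17. From WT to KO+WT, with loss counted over all 3 lists, the odds ratio was 6.88. From KO+WT to WT the odds ratio was 0.626 (95% interval 0.383 to 1.02). Outside the lists, Myo16, Fam19a5, Mad2l1, Rbm44 and Adcy1 led the genes lost in KO+5RK, and Gli3, Epb41l1, Ptpn4, Gm12688 and Usp13 those lost in KO+13RK. Several of these lost genes had a peak without METTL14, since Rnf168, Ezh2, Grb2, Rplp2 and Epb41l1 were called in all 3 KO lists and Chek1, Mad2l1, Fn1 and Prmt7 in 2. The BRCA1 complex gene Babam1 was gained in both mutants. Hnrnpa2b1, Rps3, Trib1, Nbeal1, Paip1, Cep85l and Tmem265 were gained in KO+5RK, and Clns1a, Rplp0, Cep83, Adamts7, Vma21, Kif17 and Gm44597 in KO+13RK. Most of these gained genes also had a peak in WT cells. Nbeal1, Cep85l and Cep83 were called in all 3 WT lists, and Babam1, Hnrnpa2b1, Rps3 and Paip1 in 2. Tmem265, Clns1a, Rplp0, Vma21 and Kif17 were called in 1 WT list, and Trib1, Adamts7 and Gm44597 in none. Of the genes lost in the mutants, 51 were shared, against 8.05 for independent lists over 4005 genes and 0.01 for unchanged groups simulated against the same KO+WT lists. The simulated groups lost only 7.9 genes on average, so 0.01 is not a chance value for lists as long as the real ones. Part of the excess may come from the shared KO+WT lists. The 8.05 also takes every gene as equally likely to be lost. Regions lost in a mutant ranked lower by p in KO+WT than regions kept. The probability that a kept region ranked above a lost one (AUC) was 0.851 for KO+5RK and 0.824 for KO+13RK. Weak calls missing from both mutants may therefore add to the shared genes. Per gene, Fisher's exact test of 6 against 6 lists called 0 of 9257 genes, with 186 at an unadjusted p under 0.05. Per region the same test called 0 of 21832, with 862 at an unadjusted p under 0.05.

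**Figure D3:**
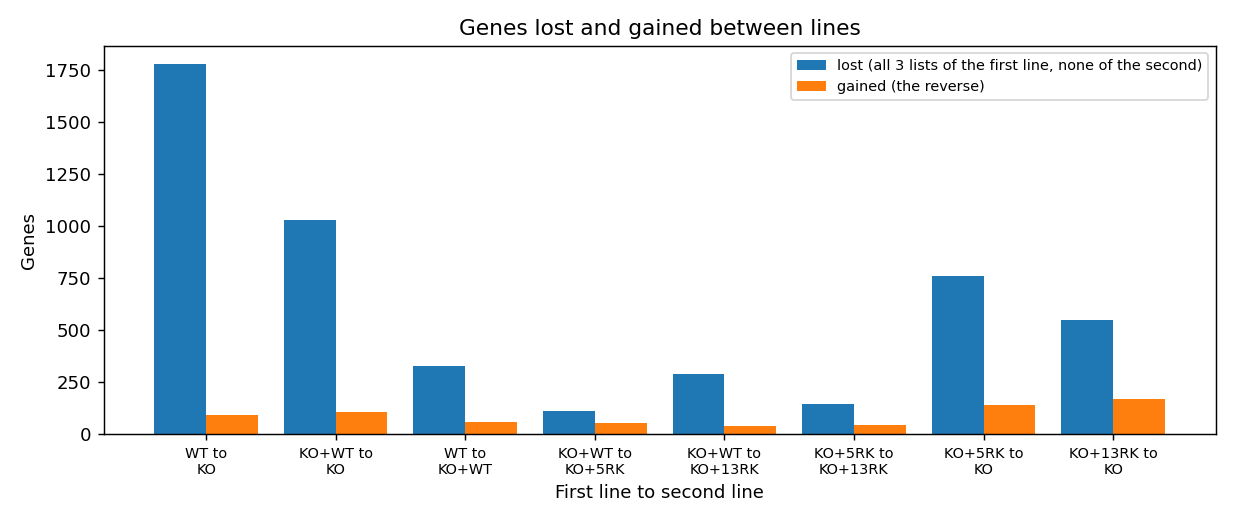
Genes lost and gained (number of genes) in each comparison of lines, where a gene is called in all 3 lists of one line and in none of the other. Bars are counts; WT to KO has 1775 lost and 94 gained genes.

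The 8744 regions called in all WT lists and no KO list, in 4085 genes, were followed into the rescue lines. KO+WT lists called 62.2% ± 2.79 of them, KO+5RK lists 48.6% ± 6.08 and KO+13RK lists 36.7% ± 3.62 (n = 3 lists per line). The lines differed (exact permutation test over the 9 lists, p = 0.00357, the smallest possible), and each pair of lines had an exact p of 0.1. The same test passed in several lists of genes after adjustment over 14 lists. No list was tested against the fall over all regions, so a pass does not set a list apart. Chromatin modifiers, for example, had 64.8% in KO+WT, 45.9% in KO+5RK and 33.3% in KO+13RK of 165 regions, close to the shares over all regions. In crosslink repair the shares were 75.7% ± 6.36, 56.9% ± 4.34 and 49.3% ± 8.42 of 48 regions (adjusted exact p = 0.025), and among pluripotency factors 72.7% ± 0.802, 56.5% ± 11.8 and 42.1% ± 6.56 of 72 regions (adjusted exact p = 0.025). Homologous recombination, arginine methyltransferases, chromatin modifiers and the TGF-beta, FGF and Wnt list also had an adjusted exact p of 0.025, excision and mismatch repair 0.0286 and the cell cycle 0.0375. End joining (0.05), noncoding RNAs (0.06), fibroblast markers (0.0864), the m6A machinery (0.0875), ribosomal proteins (0.292) and primed state markers (1) did not pass by the adjusted exact p.

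**Figure D4:**
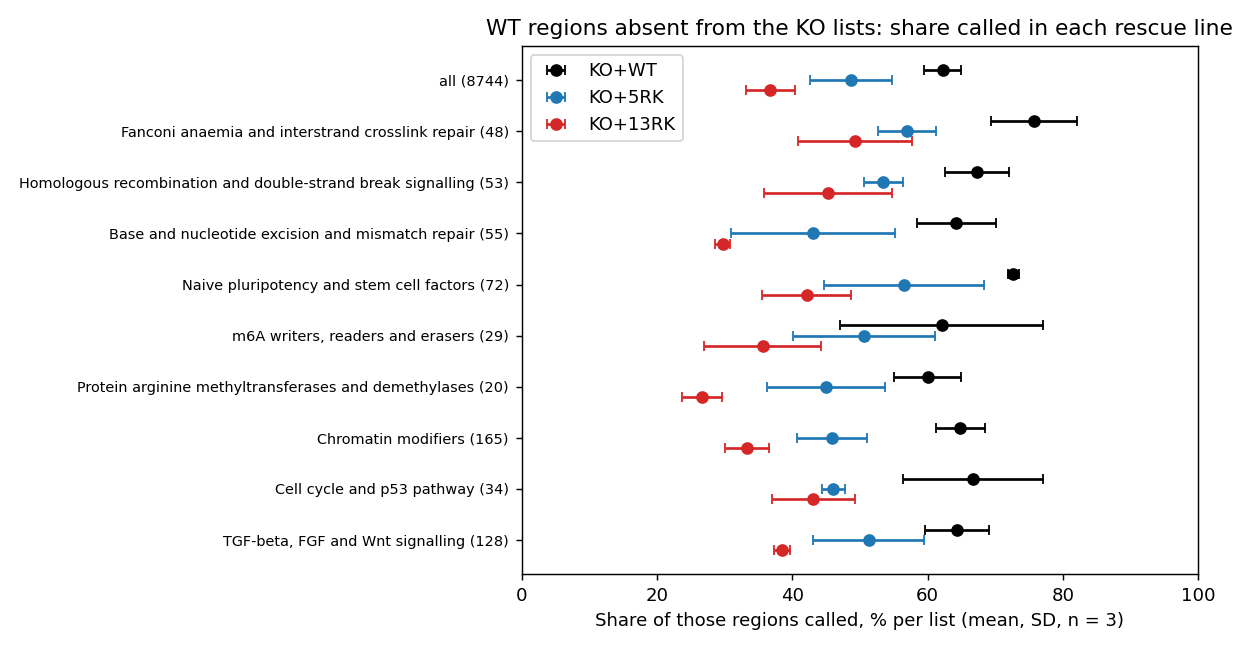
Share of the 8744 regions called in all WT lists and in no KO list that were called in each rescue line (percent per list), for all regions and for the gene lists with 20 or more of them, whose region numbers are in parentheses. Values are the mean and SD of 3 lists; over all regions they are 62.2%, 48.6% and 36.7% in KO+WT, KO+5RK and KO+13RK.

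The number of list members with a peak differed between the 5 lines in 10 of the 14 gene lists (permutation tests, adjusted over 14 lists), and in 0 of 14 at equal list length. At the stricter q it differed in 12 of 14, and the calls of 4 lists changed. Crosslink repair had 36.3 ± 0.577 members with a peak in WT, 15.3 ± 2.89 in KO, 31.7 ± 2.08 in KO+WT, 31.7 ± 1.15 in KO+5RK and 25.0 ± 3.61 in KO+13RK (n = 3; permutation test, adjusted p = 0.00021). The signalling list had 36.3 ± 0.577, 20.7 ± 4.16, 35.0 ± 1.00, 32.0 ± 2.00 and 28.0 ± 3.46 in the same order (permutation test, adjusted p = 0.00021). The adjusted permutation p was 0.00084 for chromatin modifiers, 0.00189 for end joining, 0.00364 for homologous recombination, 0.00772 for arginine methyltransferases, 0.00882 for excision and mismatch repair, 0.0244 for fibroblast markers, 0.03 for the cell cycle and 0.0363 for noncoding RNAs. Pluripotency factors (0.073), the m6A machinery (0.0809), ribosomal proteins (0.141) and primed state markers (0.821) did not pass by the adjusted permutation p. At the stricter q, pluripotency factors (0.00374), the m6A machinery (0.00374) and ribosomal proteins (0.0198) passed by the adjusted permutation p and fibroblast markers (0.145) did not. Adjusted over the list alone, the per-gene test of KO against the 12 other lists called 8 signalling genes, 2 each in crosslink repair, excision and mismatch repair, pluripotency and noncoding RNAs, 1 each among fibroblast markers, the m6A machinery and arginine methyltransferases, and 0 in the other lists. The fibroblast marker, Fbn1, was called in all 3 KO lists and in none of the 12 others, a gain in KO. The test of wild-type against mutant lists, adjusted over the list alone, called 0 in each list. The signalling list includes Fgfr2, whose bins span 2959700 nt and 12 other genes, so its calls are uncertain.

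The share of genes that lost every peak was also compared between each list and other genes, a test that does not allow for the number of peaks per gene. Chromatin modifiers, which had more peaks per gene than genes in general, passed it, and it cannot show that they were spared. From WT to KO, 5 of 54 members with a peak in all WT lists were lost (9.26%, against 31.7% of other genes; Fisher's exact test, odds ratio 0.219, adjusted p = 0.0024 over 14 lists). From KO+WT to KO, 4 of 51 were lost (Fisher's exact test, odds ratio 0.243, adjusted p = 0.0266). Against KO+5RK and KO+13RK, the KO lists had lost 2 of 44 and 1 of 39 members (Fisher's exact test, adjusted p = 0.015 and 0.031). With loss counted at 0 or 1 of 3 lists, the list no longer passed from KO+13RK to KO. The list had 56.7 members with a peak in WT, with 366 ± 7.94 peaks per list (n = 3), and genes in general had 2.89 peaks each. Its peaks numbered 133 ± 27.1 in KO, and its share of all peaks was 1.61% in WT and 1.70% in KO. No other list passed in these comparisons, and no list passed among the genes lost in KO+5RK or KO+13RK against KO+WT.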

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

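The alternatives without the gene models of long span, with unmerged bins, and all those of the region test, the share near gene starts and the regions followed in rescue lines were chosen after the data had been seen. Read depth is unknown, so how far missing calls reflect depth was not measured. Of the results that answer a comparison, 321 values were labelled as unchanged and 126 as moved. Counts were unchanged when within a fixed fold of the main value, and ratios and differences when in the same direction. The share of KO regions in all WT lists was unchanged when within the SD of the KO lists. The 321 include values that could not move, such as those of the replicate block. No single value changed sign, although the balance of lost against gained genes did. Shares by transcript part and sequence motif were to be computed as well and were not run, as no genome or transcript annotation was at hand.

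With lists of equal length, genes lost and gained were 584 and 504 from WT to KO, 500 and 325 from KO+WT to KO, 84 and 116 from WT to KO+WT, 97 and 108 from KO+WT to KO+13RK, 57 and 74 from KO+5RK to KO+13RK, and 454 and 269 from KO+5RK to KO. KO+5RK lost 54 and gained 69 against KO+WT, and 0 gene lists passed the test of members with a peak. Among lost genes, chromatin modifiers still passed from WT, KO+WT, KO+5RK and KO+13RK to KO. The balance of lost over gained genes turned in WT to KO+WT, KO+WT to KO+5RK, KO+WT to KO+13RK and KO+5RK to KO+13RK. Cutting lists to one length removes a difference in peak number by construction. The turn therefore cannot tell a real loss from lower sensitivity. The regions called in all WT lists and no KO list were defined anew at this length, so they differ from the regions followed above. The share of them that was called was still lower than in KO+WT, by -9.52 points in KO+5RK and -19.5 in KO+13RK.

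With calls in 2 or more lists against 0, more genes passed by construction, with lost and gained counts of 2710 and 364 (WT to KO), 1902 and 423 (KO+WT to KO), 877 and 299 (WT to KO+WT), 545 and 327 (KO+WT to KO+5RK), 909 and 292 (KO+WT to KO+13RK), 656 and 348 (KO+5RK to KO+13RK), 1629 and 534 (KO+5RK to KO), and 1270 and 618 (KO+13RK to KO). The mutants then shared 266 lost genes, and 29.5% of KO regions were in all WT lists. With the stricter q, gained genes were 58 in KO and 34 in KO+WT against WT, 22 in KO+5RK and 20 in KO+13RK against KO+WT, KO+13RK lost 96 and gained 28 against KO+5RK, and the KO region test called 655. With enrichment at or above the median, KO gained 60 against WT and lost 301 against KO+13RK. With loss counted at 0 or 1 of 3 lists, 2 gene lists passed from WT to KO+WT, both with fewer losses than other genes. They were homologous recombination (odds ratio 0) and chromatin modifiers (odds ratio 0.18). From KO+13RK to KO 0 gene lists passed, where chromatin modifiers had passed. For these the cause was not tested.

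Leaving out each list in turn needs fewer calls and so raises counts by construction. Gained genes ranged over 144 to 222 (WT to KO), 164 to 258 (KO+WT to KO), 208 to 334 (KO+5RK to KO) and 255 to 401 (KO+13RK to KO). Lost and gained genes ranged over 485 to 615 and 98 to 158 (WT to KO+WT), 208 to 286 and 97 to 160 (KO+WT to KO+5RK), 431 to 574 and 67 to 135 (KO+WT to KO+13RK), and 231 to 350 and 98 to 176 (KO+5RK to KO+13RK). The KO region test ranged over 0 to 1577, with 0 without KO replicate 1, 2 or 3, where 2 KO lists cannot pass. KO regions in all WT lists ranged over 34.8 to 52.2% and shared lost genes over 63 to 138.

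With the replicate block, the ratio of KO to WT peaks was 0.344 and 50 of 50 results stayed as they were. None of them could have changed. The block leaves the rule for lost and gained genes and regions, and the differences of means, as they were. The ratios were judged only by direction, between lines whose lists did not overlap. Same-numbered lists correlated at -0.0266 to 0.0201 and 3 of 15 lists correlated best with their own number, so the numbers do not pair the lists.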

Other observations

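The tests of lower sensitivity as the whole cause and of regions called in the KO lists alone, the odds ratio of near-start KO regions, the control odds ratios, the share of peaks in gene lists, the fully separated regions over 455 sets and the counts of splits of 6 lists were chosen only after the results were seen.

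The KO lists held fewer peaks than the WT lists. Lower sensitivity that keeps the peaks of smallest p cannot be the whole cause, because at equal length 16.8% of KO peaks lay near gene starts against 3.00% in WT. A loss of sensitivity that differed along genes was not tested, so lower sensitivity of that kind, or as a part of the cause, stays open. The WT regions kept in KO ranked only slightly higher in WT by p than those not called (AUC 0.576, 95% interval 0.530 to 0.614), below dropout between WT replicates (0.773 to 0.786) but not below the bound of 0.5 set beforehand. Regions called in all KO lists and none of the 12 others numbered 248, and the highest of the other sets of 3 lists, of 455 sets in all, had 925, which does not decide it either.

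The mutant lists held fewer peaks than KO+WT, and lower sensitivity of those lists may account for it. Regions kept in the mutants ranked higher by p in KO+WT than lost ones, with an AUC of 0.851 in KO+5RK and 0.824 in KO+13RK. Dropout between KO+WT replicates gave 0.739 to 0.768, and WT to KO+WT gave 0.844. At matched p percentile, regions absent from KO were lost more often than regions kept in KO, with an odds ratio of 8.05 (95% interval 5.81 to 11.2) in KO+13RK and 5.60 (3.57 to 8.78) in KO+5RK. A lower bound above 1 had been set beforehand as evidence against lower sensitivity, and both met it. That bound was wrong, because dropout within lines gave odds ratios of 1.27 to 3.17 in 12 cases. WT to KO+WT, with no arginine mutation, gave 6.88. Neither is an exact control. Dropout scores the loss from a single list, whereas the mutant ratios need loss from every list of the line. KO+WT did not regain all WT peaks, so the 6.88 may reflect an incomplete rescue as well as sensitivity. The reverse comparison, from KO+WT to the longer WT lists, went the other way, with 0.626 (95% interval 0.383 to 1.02). An effect of the mutations and lower sensitivity therefore cannot be told apart here.

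The KO peaks lay more often near gene starts. Selection of the strongest peaks in a short list was excluded, since WT lists of the same length had 3.00% near the start. Peaks independent of METTL14 that are also present in WT stay open as an explanation, since WT regions kept in KO lay near the start in 18.4% of cases and those absent from KO in 1.04%, while regions called in KO and in no WT list did so in 25.4%. KO regions near starts were in all WT lists less often than other KO regions (37.8% of 426 against 45.2% of 1578, odds ratio 0.737, 95% interval 0.592 to 0.918). A ratio below 1 had been set as evidence against that explanation, which was wrong, because the other shared regions are called without METTL14 too.

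Splits of 6 lists into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 of the 10 gave as many lost and gained genes. The real and the highest other value were 1869 and 100 (WT and KO), 1139 and 134 (KO+WT and KO), 388 and 141 (WT and KO+WT), 166 and 154 (KO+WT and KO+5RK), 326 and 150 (KO+WT and KO+13RK), 190 and 176 (KO+5RK and KO+13RK), 905 and 132 (KO+5RK and KO), and 722 and 137 (KO+13RK and KO). For the KO region test, 1 of 100 splits gave as many regions (1371, highest other 0). That test passes no region unless 1053 are fully separated, so the 0 of other splits does not mean that they separated none. Counted without the threshold, 1371 regions were fully separated between KO and the 12 other lists, and the highest of the other sets of 3 lists, the WT lists, had 930. Only 1 of the 455 sets had as many, which sets this count apart from random sets of 3 lists. The sets treat the 15 lists as interchangeable, although lists of one line are alike. With 5 lines, a chance difference between lines is not excluded. For the region test of wild-type against mutant lists the real value and the highest other were both 0, so that 100 of 100 splits gave as many by construction and the splits say nothing about chance.

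The share of a list's peaks that lay in each gene list was compared over the 5 lines by permutation tests adjusted over 14 lists. It differed for chromatin modifiers (adjusted permutation p = 0.00014), fibroblast markers (0.00273), crosslink repair, end joining and ribosomal proteins (0.0138 each) and noncoding RNAs (0.0148). It did not pass for signalling (0.0723), pluripotency (0.176), the m6A machinery and the cell cycle (0.235 each), primed state markers (0.256), arginine methyltransferases (0.543), excision and mismatch repair (0.754) and homologous recombination (0.996). Chromatin modifiers held 1.61% of the peaks in WT, 1.70% in KO, 1.82% in KO+WT, 1.45% in KO+5RK and 1.38% in KO+13RK, and crosslink repair 0.521%, 0.291%, 0.563%, 0.581% and 0.476%.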
